A study of Mus musculus with 2 samples.

How the data were processed

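Single-cell RNA libraries of mouse retina were compared, 1 from eyes taken 24 h after an intravitreal injection of NMDA and 1 from uninjured eyes. The mice carried Glast-CreERT2, a tamoxifen-inducible Cre recombinase active in Müller glia and astrocytes, and the ROSA26R-Ai9 allele, which gives tdTomato fluorescence after recombination. Per the labels, tamoxifen was given at 75 mg/kg on 5 consecutive days, the injection was 2 microlitres of NMDA at 100 mM, the other eye was left without injection, and tdTomato-positive cells were sorted and loaded on the 10x Chromium 3' platform. NMDA is a glutamate receptor agonist that kills inner retinal neurons by excitotoxicity. The number of animals behind each library is not given in the sources used here.

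The deposited matrices hold whole-number UMI counts per gene and barcode, which the authors made with Cell Ranger 6.0.1, per the file headers. The genome build mm10 and the tools Cell Ranger and Seurat are named in the submitters' processing notes. Cell-calling settings and the annotation release are not given in the sources used here. Both matrices list 21886 features, of which 2 are transgene sequences named tdT and GFP. Of these features, 21779 identifiers matched the GENCODE M21 annotation of the same build, which supplied the coordinates printed here.

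Everything from the counts onward was computed for this work with Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Plots were drawn with matplotlib 3.10.9. Kept barcodes had at least 500 genes, at least 1000 UMIs and at most 20% mitochondrial UMIs. The automatic threshold of Scrublet marked 0 barcodes in the NMDA library and 5 in the uninjured library, which was taken as a failure of that caller. Whether doublets had been removed before deposit is not given in the sources used here. By a rule set beforehand, the barcodes with the highest Scrublet scores were removed from each library instead, at 0.8% per 1000 barcodes. This left 4166 of 4701 barcodes in the NMDA library and 2152 of 2833 in the uninjured library. The cell filter took out 358 and 618 barcodes respectively, and the doublet rule another 177 and 63.

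Kept cells of both libraries were clustered together without integration, on 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method at resolution 0.5, which gave 13 clusters. A cluster took the name of the class whose fixed markers had the highest mean share of cells with a UMI, unless another class had at least 2 markers, and more, among the cluster's top 10 genes by fold. It stayed unnamed with under 3 markers each detected in 25% of its cells, with more top genes from another class, or with a low median UMI count and no own marker among the top genes. Under that rule, no Müller glia-like cluster could have more markers of another class than of its own among those top genes. This was therefore no check of identity. Clusters 1, 3, 4 and 7 had 0 of their own markers and 0 of other classes there. Clusters 0 and 12 had 1 of their own and 1 of another class. In cluster 7, 7 of 12 Müller glia markers were each detected in at least 25% of cells.

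UMIs were summed over the Müller glia-like cells of each library and given as CPM, the count of a gene per 1000000 UMIs of that sum. The log2 ratio of NMDA over uninjured had 0.5 counts added to both sums. Genes with at least 10 CPM in the mean of both libraries were counted. Intervals are 95% intervals: exact Poisson for a sum, exact conditional binomial for a ratio and Clopper-Pearson for a share. They cover counting error only and say nothing about the spread between animals. With 1 library per group there is no replicate check, so no p-value was computed, and genes are described by the size of the difference. "Higher" and "lower" in a count mean at least a 2-fold ratio. A fold against a count of 0 is a lower bound, taken against 3 UMIs, and the limit given with a share of 0 is 3 cells of the total.

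Before the data were examined, 30 gene lists, 19 marker lists and the rule for named genes were fixed. Some lists share genes. The rule for named genes took the 10 largest and the 10 smallest ratios among genes with at least 50 CPM in the mean of both libraries, at least 50 UMIs and a counting interval excluding 2-fold, leaving out predicted, mitochondrial and sex-linked genes and markers of other cell types. It added up to 4 members of each list with the largest ratios, and Gfap, Vim, Glul, Rlbp1, Slc1a3, Aqp4, Kcnj10, Piezo1, Trpv4 and Yap1. In rod-like cells it took the 5 largest and the 5 smallest ratios. Genes outside the rule that spell out a count of 5 or fewer, the leading genes of clusters, and the sequences tdT and GFP were named after their values were seen. Some genes that the rule picks are not reported here. The median ratio of each list was placed among the medians of 10000 random lists of the same size matched on expression in 10 bins. Those percentiles describe these libraries and are not tests.

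For shares of cells with a UMI and for list scores per cell, cells were thinned to 2000 UMIs. The ratio and list functions were tested on simulated counts for this comparison with 200 changed genes, in a step that ran on the 8974 genes past the limit on low genes. All 65 genes simulated at 3-fold and all 59 at 8-fold were found at least 2-fold apart in the right direction, as were 0 of the 66 genes simulated at 1.5-fold and 0 of 8784 unchanged genes. Alternatives covered the cell filter, doublets, clustering resolution, scaling, with TMM factors from edgeR 4.0.16 in R 4.3.3, weighting and thinning of cells, free RNA, the filter on low genes and the added count. Free RNA was estimated from rod markers, with barcodes under 1000 UMIs or 500 genes as its profile, at 0.67% of the Müller glia-like sum in the NMDA library and 0.86% in the uninjured library. That profile rests on 229 and 114 deposited barcodes with low counts, not on empty droplets.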

Results

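The transcriptomes of sorted tdTomato-positive retinal cells were compared between an NMDA library, taken 24 h after injury, and an uninjured library. The series addresses retinal stiffness during reactive Müller gliosis, the response of the main glial cell of the retina to damage, and pairs it with Brillouin microscopy, a light-scattering measure of mechanical properties that was not analysed here. Each group was represented by 1 library, so every difference below lies between those libraries. The NMDA library held 4701 barcodes and 79523805 UMIs, with a median of 17343 UMIs and 4663 genes per barcode. The uninjured library was shallower, with 2833 barcodes, 17929924 UMIs and medians of 6060 UMIs and 2837 genes.

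Most kept cells of both libraries were Müller glia-like. They made up 77.7% of 4166 NMDA cells (95% interval 76.5 to 79.0%) and 93.2% of 2152 uninjured cells (92.1 to 94.2%). A further 16.9% of NMDA cells and 0.28% of uninjured cells stayed unnamed. Nearly all of these belonged to a low-UMI cluster of 694 cells led by Ercc1, Ccl5 and ribosomal protein genes, whose detected markers were mostly those of Müller glia. Counted with the Müller glia-like class, a choice made after seeing the data, the unnamed cells brought the NMDA share to 94.6%. Rod-like cells formed 4.13% and 5.44% of the libraries, with 172 and 117 cells. Microglia- or macrophage-like cells numbered 30 in the NMDA library and 2 in the uninjured library, cone-like cells 7 and 13, astrocyte-like cells 8 and 6, and bipolar-like cells 8 and 2. The tdTomato gate and the depth gap can set these shares. The reporter transcript itself was at 52.4 CPM in NMDA Müller glia-like cells and 42.0 in uninjured ones, and was seen in 61.5% and 26.3% of those cells without thinning, at median depths of 20607 and 7490.5 UMIs. After thinning to 2000 UMIs the shares were 9.76% and 8.14%. In rod-like cells, which should lack it, the unthinned share was 1.7% in both libraries, at medians of 1606 and 1771 UMIs.

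Müller glia-like cells of the libraries fell into separate clusters. Of the 2006 uninjured cells, 1804 lay in cluster 0, led by Hes5 and Glul, and 189 in the low-UMI cluster 12, led by the cone opsin gene Opn1sw, E130218I03Rik and Glul. The 3239 NMDA cells lay mainly in cluster 3 (1885 cells), cluster 4 (760 cells) and cluster 1 (509 cells), with 76 in cluster 7. Cluster 3 was led by Prss56, St8sia5 and Olfm2. Cluster 4 was led by Hbegf, Hmga2, Upp1 and Plaur, and cluster 1 by Lcn2, Serpina3n and Gfap. Cluster 7 was led by Gm13889, Cxcl2, Ifi203 and Areg. These genes describe the clusters, which may be libraries rather than cell types.

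The question put to the Müller glia-like sums was how expression differed 24 h after NMDA. The NMDA library showed the profile of reactive glia with a loss of transcripts of mature Müller glia. Gfap, the intermediate filament gene used as the classical marker of gliosis (ENSMUSG00000020932, chromosome 11, 102887336 to 102900912, minus strand, mm10), was at 435 CPM against 48.2, a 9.03-fold difference with a log2 ratio of 3.18 (counting interval 3.07 to 3.28). Glul, which encodes glutamine synthetase (ENSMUSG00000026473, chromosome 1, 153899944 to 153909723, plus strand), was 23.9-fold lower, at 863 against 20596 CPM. Of 8927 genes with at least 10 CPM, 669 were at least 2-fold higher and 1582 at least 2-fold lower in the NMDA library. The balance of directions depended on scaling. Higher genes were 29.7% of those 2-fold apart with CPM, 61.3% with TMM factors, 48.2% with the median of ratios and 47.3% when ribosomal protein and mitochondrial genes were left out of the scaling. The median gene had a log2 ratio of -0.25, and those scalings moved it by 0.41, 0.25 and 0.24. Ratios below are from CPM, to be read against that median.

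**Figure D1:**
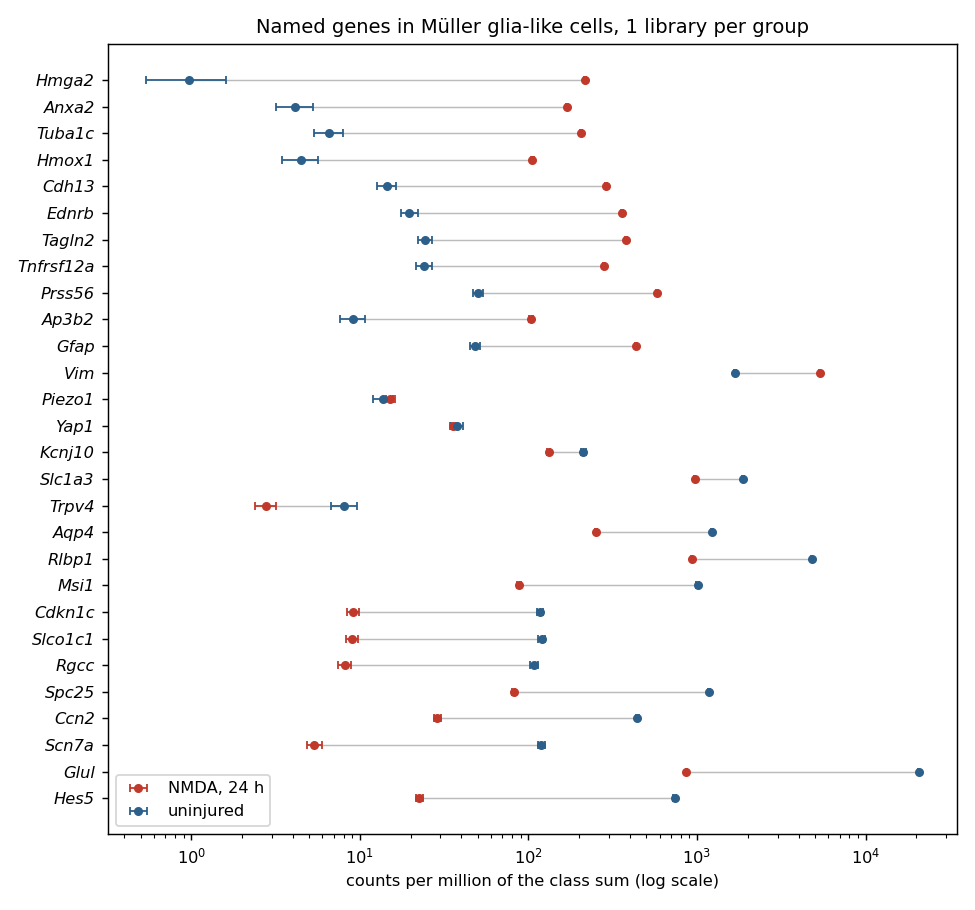
CPM (x axis, log scale) of genes from the 10 largest and 10 smallest ratios and of the genes always named, in Müller glia-like sums of the NMDA (red) and uninjured (blue) libraries; bars are 95% Poisson counting intervals. Piezo1 and Yap1 lie close together in both libraries, while Hmga2 and Glul lie over 20-fold apart in opposite directions.

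Genes of reactive gliosis were higher as a group. Of 19 measured members, 12 were at least 2-fold higher and 2 lower, and the median log2 ratio of 1.48 lay at percentile 100.0 of random lists. Beyond Gfap, the members named by rule were Emp1, a membrane protein gene (log2 ratio 5.55), the chemokine gene Ccl2 (3.34) and Timp1, an inhibitor of matrix metalloproteinases, at 171 against 18.5 CPM. The lower members were Socs3, a feedback inhibitor of cytokine signalling, and A2m, a protease inhibitor. Genes of resting Müller glia moved the other way, with 16 of 23 lower, 2 higher and a median of -1.73 (percentile 0.0). The Notch effector gene Hes5 was 32.6-fold lower and the lipid transporter gene Abca8a 9.53-fold lower, while Rlbp1, the retinaldehyde-binding protein of the visual cycle, was 5.12-fold lower at 932 against 4775 CPM. The 2 higher members were Prss56, a serine protease gene linked to eye size (577 against 50.3 CPM), and Crym, a thyroid hormone-binding protein gene. Of the 12 markers used to name the class, 9 were at least 2-fold lower and 0 higher, with a median of -2.36.

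Transcripts for glutamate, potassium and water handling were lower, 9 of 16 with 0 higher and a median of -1.64 (percentile 0.0). The glutamate transporter gene Slc1a2 was 7.75-fold lower and the amino acid transporter gene Slc38a3 5.67-fold. The water channel gene Aqp4 was 4.87-fold lower, at 251 against 1222 CPM. Slc1a3, the glial glutamate transporter whose promoter drives the Cre line, and Kcnj10, the main potassium channel, differed by less than 2-fold, with log2 ratios of -0.94 and -0.67.

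The largest ratios among well-expressed genes were those of Hmga2, a chromatin architecture gene of embryonic and transformed cells (14982 against 15 UMIs, log2 ratio 7.76), Anxa2, a membrane- and actin-binding annexin (5.34), the tubulin gene Tuba1c (4.96), Hmox1, which encodes haem oxygenase (4.55), Cdh13, an atypical cadherin (4.32), the endothelin receptor gene Ednrb (4.18), the actin-binding gene Tagln2 (3.96), the TWEAK receptor gene Tnfrsf12a (3.54), Prss56 (3.52) and Ap3b2, an adaptor complex subunit (3.51). At the other end stood Hes5 (-5.03), Glul (-4.58), the sodium channel gene Scn7a (-4.47), Ccn2 (-3.94), the kinetochore gene Spc25 (-3.84), the cell cycle regulator gene Rgcc and the thyroid hormone transporter gene Slco1c1 (both -3.73), Cdkn1c, an inhibitor of the cell cycle (-3.68), and the RNA-binding protein gene Msi1 (-3.52). By the same size rule without the limit of 10 each way, 340 genes qualified as higher and 558 as lower.

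**Figure D2:**
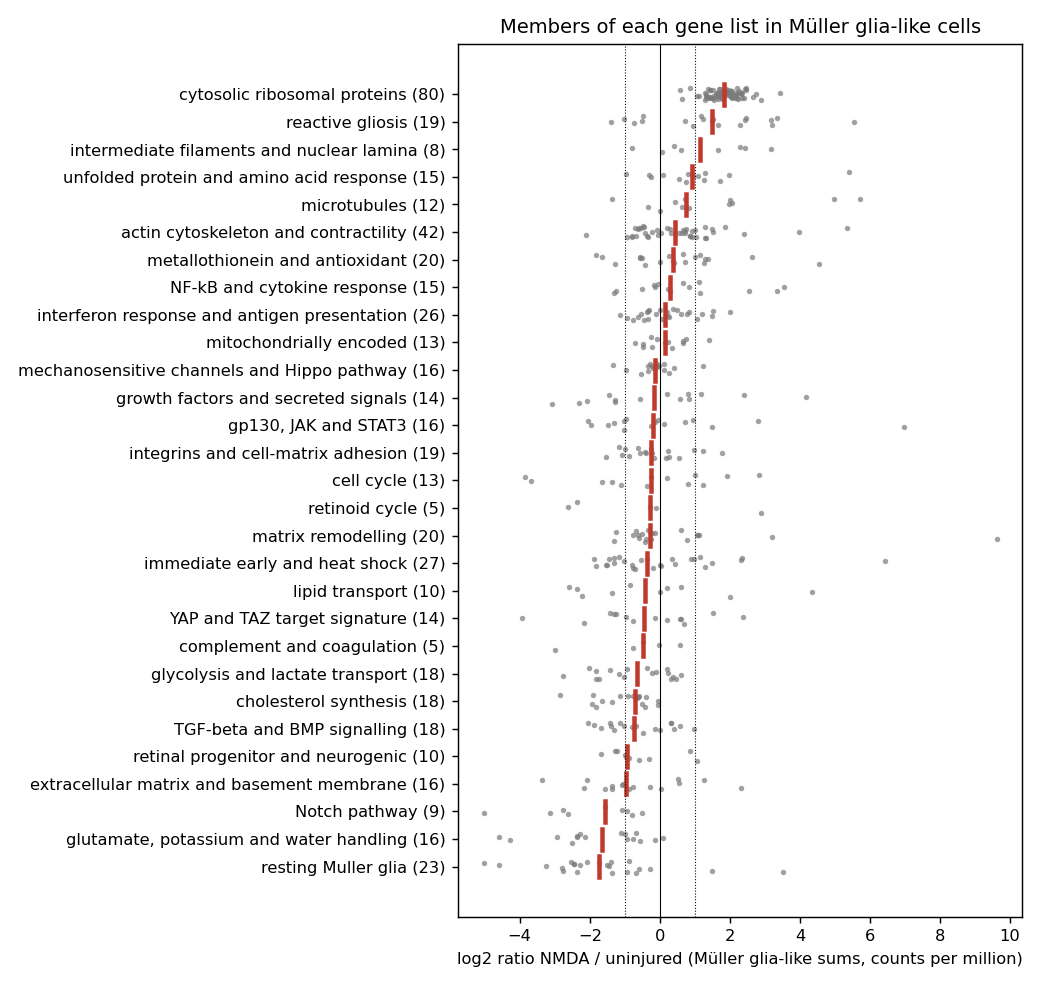
Log2 ratio of NMDA over uninjured (x axis) for each measured member (grey points) of the gene lists (y axis, number of measured members in brackets) in Müller glia-like sums, with list medians as red bars and dotted lines at 2-fold; sex-linked genes are not drawn, and the point of Plaur rests on 0 uninjured UMIs. Medians run from -1.73 for resting Müller glia to 1.82 for ribosomal proteins, and 8 medians between -0.36 and -0.15 change sign under at least 1 other scaling.

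Lists of cytoskeletal genes, which bear on cell mechanics, had more members higher than lower in the NMDA library. Intermediate filament and nuclear lamina genes had 4 of 8 members higher and 0 lower (median 1.14, percentile 100.0): Gfap, Nes (log2 ratio 2.43), Lmna, which encodes lamins A and C (2.30), and Vim, at 5330 against 1672 CPM. Of 42 actin and contractility genes, 10 were higher and 1, the myosin light chain gene Myl9 (-2.11), was lower, with a median of 0.43 (percentile 100.0). Besides Anxa2 and Tagln2, the actin-capping protein gene Capg had a log2 ratio of 2.41. With TMM factors 20 actin genes were at least 2-fold higher. Microtubule genes had 5 of 12 higher and 1 lower (median 0.76, percentile 99.4). The higher ones were Tubb6 (5.71), Tuba1c, Tubb2b (2.05), Map1b (2.00) and Tubb5, and the lower one was Stmn1, a tubulin-binding protein gene. Tubulin genes are close paralogs, so single members are less certain than the group.

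More extracellular matrix genes were lower than higher. Of 16 measured matrix and basement membrane genes, 8 were lower and 2 higher, with a median of -0.97 (percentile 0.2). The collagen genes Col9a1 and Col23a1 were 10.4-fold and 4.47-fold lower and the secreted adhesion gene Spon1 4.22-fold lower, whereas the fibrillar collagen gene Col11a1 was 4.95-fold higher. Gpc1, a glypican gene, was the other higher member. With TMM factors 4 of these genes were lower. Matrix remodelling genes went both ways, 5 higher and 2 lower of 20, with a median of -0.29 (percentile 30.9) that turned positive with TMM factors. Plaur, the urokinase receptor gene, had 1757 UMIs in NMDA and 0 in uninjured cells, at least 131.4-fold higher; with it at that bound the median stayed at -0.29. Timp1, Plod3 and the cathepsin genes Ctsb and Ctsd were the other higher members, and Plod2 (-1.26) and P4ha1 (-1.31), enzymes of collagen modification, were the lower ones. Integrin and adhesion genes split into 2 higher, Cd63 (1.78) and Cd44 (1.22), and 3 lower, Itgb5 (-1.54), Sdc2 (-1.17) and Cd81, of 19; their median of -0.24 (percentile 29.2) was at or above 0 with all other scalings.

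Mechanosensitive channel and Hippo pathway genes showed little difference by size. Of 16 members, 1 was higher, Wwtr1 (log2 ratio 1.23), which encodes the coactivator TAZ, and 1 lower, the channel gene Trpc1 (-1.34). The median of -0.15 (percentile 75.3) was positive with every other scaling, and 0.12 at 50 CPM. For Piezo1, the stretch-activated channel gene (chromosome 8, 122481698 to 122551329, minus strand), CPM showed no difference beyond counting error. It was at 15.1 against 13.8 CPM, with a log2 counting interval of -0.08 to 0.36. The other scalings put its log2 ratio between 0.37 and 0.54, so this reading depends on scaling. Yap1 was also level at 35.8 against 37.9 CPM (-0.21 to 0.05), and at 0.16 to 0.33 with the other scalings. Trpm7 (-0.53) and Lats2 (-0.97) differed by less than 2-fold. Trpv4, a calcium channel gene, lay below the limit for counted genes, with 190 and 125 UMIs, at 2.76 against 8.08 CPM and a log2 ratio of -1.55 (-1.88 to -1.21). Among 14 genes of a YAP and TAZ target signature 5 were lower and 2 higher, with a median of -0.46 (percentile 15.8) that was 0.21 over genes with at least 50 CPM. Ccn2, a matricellular factor and common readout of YAP activity (chromosome 10, 24595442 to 24598683, plus strand), was 15.4-fold lower and Amotl2 4.53-fold lower, followed by Crim1, Ajuba and Ccn1. Gadd45a (2.36) and the receptor gene Axl (1.51) were higher.

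The NF-kB and interferon lists had medians slightly above 0. NF-kB and cytokine genes had 5 of 15 higher, namely Tnfrsf12a, Ccl2, Cxcl12 (2.54), Nfkb2 and Tnfrsf1a, and 2 lower, Irf1 (-1.32) and Vcam1, with a median of 0.28 (percentile 98.4). Interferon response and antigen presentation genes had 5 of 26 higher, Rtp4 (2.01), Ifitm3 (1.52), Bst2 (2.83-fold), B2m (1.19) and Psmb10, and 1 lower, H2-T23, with a median of 0.14 (percentile 98.2). The list for gp130, JAK and STAT3 split into 3 higher and 6 lower of 16. Myc (log2 ratio 6.98), the cytokine gene Clcf1 (2.80) and Osmr were higher, and the lower members included the ligand and receptor genes Ctf1 (-2.05) and Cntfr (-1.98). Its median of -0.20 (percentile 45.7) was positive with the other scalings. Complement and coagulation genes, 5 measured, had 0 members at least 2-fold higher and a median of -0.49 (percentile 27.1), with F3 at 0.58, C4b at -0.49 and Cd59a at -0.78.

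In the Notch and TGF-beta lists more genes were lower than higher. Of 9 measured Notch genes 6 were at least 2-fold lower and 0 higher (median -1.57, percentile 0.0), among them Hes5, Hes1 (-2.76), Nrarp (-3.14) and Notch2 (-2.62). TGF-beta and BMP genes had 8 of 18 lower and 0 higher, with a median of -0.74 (percentile 1.5); Bambi (-2.04), Id4 (-1.88), Smad6 (-1.67) and Id3 (-1.43) led. Retinal progenitor and neurogenic genes included the transcription factor genes Pax6 (-1.68) and Rax (-1.27), both lower, and had 1 of 10 higher, Sox4 (1.07), with a median of -0.93 (percentile 1.6). Growth factor and secreted signal genes went both ways, 3 higher and 6 lower of 14. Ednrb, the growth factor gene Hbegf (2.41) and Fgf2 were higher, while Vegfa (-3.08) and Igfbp5 (-2.30) were lower. Their median of -0.17 (percentile 62.4) turned positive with the other scalings and with at most 10% mitochondrial UMIs per cell. Cell cycle genes also split, 4 higher and 5 lower of 13 (median -0.26, percentile 42.4, positive with TMM factors and with no limit beyond 1 UMI). Cdkn1a (2.83), Ccnd1 (1.91), Mcm2 and Cdk4 were higher, and Spc25, Cdkn1c, Cdkn2c, Cdkn1b and Ccnd3 lower.

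Metabolic and stress genes differed by pathway. Cholesterol synthesis genes had 7 of 18 lower and 0 higher (median -0.70, percentile 1.7), among them Insig1 (-2.84) and Srebf2 (-1.82). Glycolysis and lactate transport genes had 8 of 18 lower and 0 higher (median -0.66, percentile 1.7), among them Aldoc (-2.76), Bsg (-2.02), Eno1 (-1.82) and Slc2a1 (-1.81). Lipid transport genes had 4 of 10 lower, Acsl3 (-2.60), Apoe (-2.36), Apoc1 (-2.21) and Clu, and 2 higher, Fabp5 (4.35) and Abca1 (median -0.43, percentile 19.3). In the retinoid cycle, Dhrs3 (-2.63) and Rlbp1 were lower, and Rdh10 was at -0.29, of 5 genes with a median of -0.29 (percentile 33.2); both turned positive with TMM factors. Unfolded protein and amino acid response genes had 6 of 15 higher and 0 lower (median 0.91, percentile 100.0), with asparagine synthetase, Asns, at 5.40, Sdf2l1 at 1.96, Manf at 1.72 and Hspa5 at 1.30. Antioxidant and metallothionein genes had 6 of 20 higher and 3 lower (median 0.38, percentile 97.8). Hmox1 and Srxn1 (2.63) stood highest, and Nqo1 (-1.82), Prdx6 (-1.66) and Mt3 were lower. Immediate early and heat shock genes had 6 higher and 9 lower of 27 (median -0.36, percentile 10.3, positive with TMM factors). Fosl1 (6.43) and the near-identical pair Hspa1a (2.33) and Hspa1b (2.35), whose reads cannot be fully told apart, were higher, and Btg2 (-1.89) was lower. All the lower members were immediate early genes, and all the higher members except Fosl1 were heat shock genes. The pooled median therefore mixes opposite directions.

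Ribosomal protein genes were higher almost throughout, 77 of 80 with 0 lower and a median of 1.82 (percentile 100.0). They took 19.1% of Müller glia-like UMIs in the NMDA library and 5.28% in the uninjured library. Rpsa (3.42), Rpl12 (2.90), Rps2 (2.74) and Rplp0 (2.66) led the list. The ribosomal share also differed in rod-like cells, at 16.8% against 8.10%. Mitochondrially encoded genes took 6.44% and 6.80% of Müller glia-like UMIs, with 1 of 13 members higher, mt-Nd6 (1.40), 0 lower and a median of 0.14 (percentile 55.6), which was -0.20 without the cell filter. The Y-linked genes Kdm5d (-1.21), Uty (-1.09) and Ddx3y (-1.06) were lower, and Eif2s3y was at -0.31, or 0.10 with TMM factors (median -1.07 over 4 genes, percentile 4.1). The sex of the animals in each library is not given in the sources used here.

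**Figure D3:**
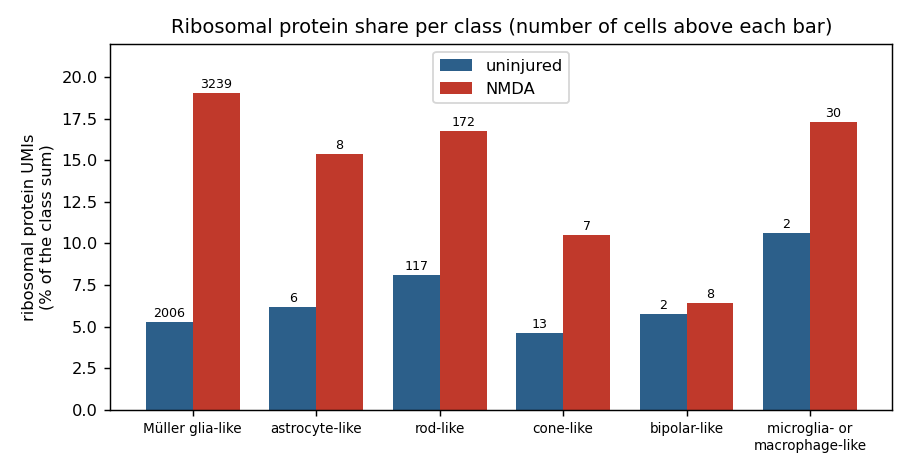
Share of UMIs from cytosolic ribosomal protein genes (y axis, percent of the class sum) per cell class in the uninjured (blue) and NMDA (red) libraries, with the number of cells above each bar. The NMDA bar is the higher in each class drawn, with 6.41% against 5.76% in bipolar-like cells and 19.1% against 5.28% in Müller glia-like cells.

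Rod markers gave few UMIs in the Müller glia-like sums. They made up 0.027% of the NMDA sum and 0.034% of the uninjured sum, and 2 of 10 measured rod markers, Sag and Pdc, were lower (median -0.48). Single measured members were lower for astrocytes (Agt, -4.40), horizontal cells (Septin4, -2.09) and pericytes (Pdgfrb, -2.61), as were 2 of 2 for ganglion cells, Thy1 and Rbpms (median -1.84), and 1 of 2 for endothelial cells, Flt1 (median -1.10). Agt was also among the top 10 genes of cluster 0, the main uninjured Müller glia-like cluster. Its lower level therefore cannot be read as less astrocyte RNA. The measured bipolar, microglia and lens markers, 1 each, differed by less than 2-fold, at 0.69, 0.12 and -0.01. The cone, amacrine, monocyte or neutrophil, lymphocyte, retinal pigment epithelium, melanocyte, fibroblast, erythroid and oligodendrocyte lists had 0 members at 10 CPM.

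Resting scores of nearly all NMDA cells lay outside the uninjured range, whereas gliosis scores overlapped it. With cells thinned to 2000 UMIs, which left out 10 NMDA and 66 uninjured cells, the resting list gave a median of 100 UMIs per 10000 in NMDA cells (quartiles 70 and 130) and 470 in uninjured cells (410 and 520). Only 0.46% of NMDA cells lay inside the central 95% range of uninjured cells. The gliosis list gave medians of 95 (70 to 120) and 35 (25 to 45), and 49.2% of NMDA cells (counting interval 47.5 to 51.0%) lay inside the uninjured range. Without thinning those shares were 0.40% and 42.1%, and the gliosis share also moved with depth, so it does not count cells that stayed unchanged. Both scores are plain sums of UMIs, so abundant members weigh most. In the resting list that was Glul, at 20596 CPM in the uninjured and 863 in the NMDA sum. In the gliosis list it was Vim, at 1672 and 5330 CPM respectively.

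**Figure D4:**
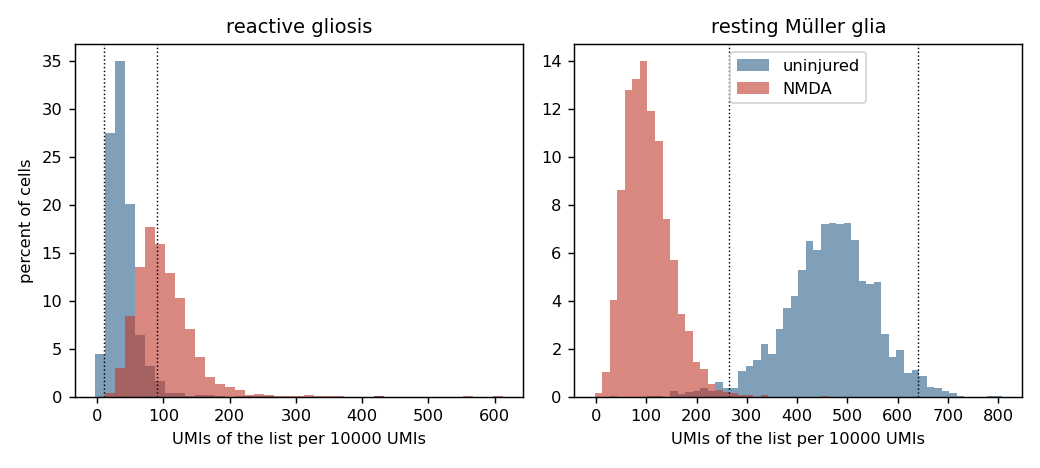
Percent of Müller glia-like cells (y axis) by UMIs of the reactive gliosis list (left) and of the resting Müller glia list (right) per 10000 UMIs (x axis), thinned to 2000 UMIs, in the uninjured (blue) and NMDA (red) libraries; dotted lines bound the central 95% of uninjured cells. The resting score parts the libraries almost fully, with 99.5% of NMDA cells below the uninjured range, while 50.8% of NMDA cells lie above the range of the gliosis score.

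At that depth, Gfap UMIs were seen in 33.2% of NMDA Müller glia-like cells (31.6 to 34.9%) and 2.99% of uninjured ones (2.28 to 3.85%). The unthinned shares were 71.0% and 6.58%, at medians of 20607 and 7490.5 UMIs. Rod-like cells, at medians of 1606 and 1771 UMIs, gave 9.3% in the NMDA library and 0 of 117 cells in the uninjured one. That 0 allows a share of cells with a UMI of up to 2.56%. Thinned to 1000 UMIs, Gfap was seen in 22.97% of NMDA Müller glia-like and 5.23% of NMDA rod-like cells. In the uninjured library it was seen in 1.94% of Müller glia-like cells and 0 of 117 rod-like cells. Vim was seen in 99.7% and 93.9% of thinned cells, Glul in 75.3% and 99.9%, Rlbp1 in 74.7% and 99.8%, Slc1a3 in 81.8% and 94.9%, Aqp4 in 38.3% and 86.8%, and Kcnj10 in 22.6% and 33.4%. The unthinned shares of these genes were 99.97% and 98.95% for Vim, 99.5% and 99.95% for Glul, 98.1% and 99.9% for Rlbp1, 99.7% and 97.1% for Slc1a3, 93.1% and 96.2% for Aqp4, and 79.0% and 70.2% for Kcnj10. Without thinning, Vim was seen in 44.8% and Glul in 19.8% of NMDA rod-like cells, and in 5.13% and 27.4% of uninjured ones. Thinned to 1000 UMIs, Vim was seen in 97.9% of NMDA Müller glia-like and 34.88% of NMDA rod-like cells. In the uninjured library Vim was seen in 77.22% and 1.71%. Glul shares at 1000 UMIs were 52.82% and 9.3% in the NMDA library and 99.7% and 21.37% in the uninjured library. Piezo1, in 3.28% and 2.47% of thinned cells, Trpv4, in 0.77% and 1.44%, and Yap1, in 7.03% and 7.22%, gave about 1 UMI or less per cell and are read as levels only.

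In rod-like cells, the only other class with 50 cells in both libraries, some genes abundant in Müller glia-like cells were higher in the NMDA library. They are called glial here and below by that abundance, since the source of the UMIs was not shown. The largest ratios included those of Gfap (51 against 0 UMIs, at least 10.5-fold higher), S100a6, and the metallothionein genes Mt2 (105 against 1 UMI, log2 interval 3.52 to 11.35) and Mt1 (5.25). All of these were more abundant in NMDA Müller glia-like cells than in these rod-like sums. The smallest were Guca1a, which encodes a photoreceptor guanylate cyclase activator, 7.52-fold lower at 43.6 against 337 CPM, Dtx3 (-2.47), Rabgef1 (-2.41), Kpna2 (-2.29) and Pdzph1 (-2.21). Of the 14 rod markers 9 were at least 2-fold lower and 0 higher, with a median of -1.36. Of 11 measured Müller glia markers 1 was higher and 1 lower, with a median of 0.59. Reactive gliosis genes were higher in 11 of 11 measured members (median 3.40), as were 11 of 11 interferon genes (median 3.06) and 39 of 80 ribosomal protein genes (median 0.98). The gliosis and interferon lists each hold 26 members, and in sums this small a gene can pass the 10 CPM limit through the NMDA library alone. The counts of 11 of 11 are therefore partly set by that limit. Their medians also rest on ratios against few uninjured UMIs, or 0 for Gfap. The rod-like sums held 344005 and 213861 UMIs, at medians of 1606 and 1771 UMIs per cell.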

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

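The tests on GFP were chosen after its values were seen. GFP, a sequence in the feature list that the labelled genotype does not name, gave a signal outside the gene comparison. In rod-like cells it stood at 880.8 CPM in the NMDA library (counting interval 784.4 to 985.8) against 116.9 in the uninjured library (75.7 to 172.6). It was seen in 58.1% of 172 NMDA rod-like cells and 13.7% of 117 uninjured ones. The few cone-like cells also held GFP, at 365 CPM in 7 NMDA cells (219.7 to 570) and 225.5 in 13 uninjured cells (131.4 to 361.1), against 93.5 in uninjured Müller glia-like cells. GFP was not confined to photoreceptor-like cells. It was seen in 48.8% of NMDA and 30.4% of uninjured Müller glia-like cells, which were deeper. Astrocyte-like cells held it at 29.2 CPM in 8 NMDA cells and 175.8 in 6 uninjured cells. It was also among the top 10 genes of cluster 5, 14 unnamed NMDA cells. Free RNA with the make-up of the Müller glia-like sum could give at most that sum's level, 82.3 CPM in the NMDA library. The value of 880.8 argues against such free RNA. In GFP UMIs per cell the classes were close, with 303 UMIs in 172 rod-like cells and 5676 in 3239 Müller glia-like cells. Their median depths were 1606 and 20607 UMIs, so the gap in CPM goes with depth. Reads of tdTomato counted as GFP would keep their ratio across classes, but there were 101.0 GFP UMIs per tdTomato UMI in rod-like cells (34.2 to 492.5) against 1.57 in Müller glia-like cells. In NMDA rod-like cells GFP was at 1300.7 CPM in the 124 cells with less glial RNA and 319.3 in the 48 with more, whereas 9 of 14 rod markers were lower than in the uninjured library and 0 higher (median -1.36). Free RNA of another make-up, misassigned reads of a photoreceptor transcript and a further transgene in some animals were not tested and stay open. An effect of the injury on GFP was not tested.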

How the results depend on the processing

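Alternatives that counted the class with its unnamed clusters, used only clusters of 500 cells or more, or scored cells thinned to 1000 or 3000 UMIs were chosen after seeing the data. No list median or named gene that was at least 2-fold apart changed sign under the settings run; medians nearer 0 that did are given beside their values. Of 2048 gene ratios recomputed 1432 stayed within the main counting interval and 616 did not; of 480 list medians 412 moved by at most 0.25 and 68 by more; of 960 counts of list members 858 stayed within 1.5 times and 102 did not; of 40 shares of cells with a UMI 36 moved beyond the main interval when thinned to another depth. Genes at least 2-fold higher and lower numbered 1337 and 845 with TMM factors, which shift every ratio up, 374 and 624 at 50 CPM, where fewer genes are tested, and 1163 and 4230 with no filter beyond 1 UMI in both libraries, where more are tested. All 669 higher and 845 of the 1582 lower genes stayed at least 2-fold apart in the same direction with TMM factors. TMM also gave 20 higher actin genes and 4 lower matrix genes. The 2 lower gliosis genes became 1 with doublets kept, the median of ratios, scaling without ribosomal genes and 50 CPM, and 0 with mitochondrial UMIs at most 10%, no cell filter, TMM, cells weighted alike and thinned cells. At 50 CPM 0 actin genes were lower, 0 matrix genes higher and 5 lower; at 1 UMI 2 intermediate filament and 3 actin genes were lower, and 5 matrix genes higher and 25 lower. The Müller glia-like share of NMDA cells was 88.92% with mitochondrial UMIs at most 10%, 68.7% with no cell filter, 79.25% with doublets kept, 79.12% with the automatic doublet threshold and 94.6% with the unnamed clusters; of uninjured cells it was 97.28% and 91.55% under the first 2. The share of NMDA cells inside the uninjured range was 60.05%, 46.4% and 42.08% for gliosis at 1000 UMIs, 3000 UMIs and without thinning, and 1.17% and 0.25% for resting genes at 1000 and 3000 UMIs. Beyond these constructions the cause was not tested. Depth limits genes near 10 CPM, and 1 library per group limits all differences.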

Other observations

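The tests of ribosomal share between classes and of glial RNA in rod-like cells were chosen after related values were seen, and the depth-matched test was set before its result. Among cell cycle genes, the inhibitor Cdkn1c in Müller glia-like cells was at 9.11 against 117 CPM, whereas Ccnd1, a driver of cell cycle entry, was at 379 against 101. This pair does not stand for the list, which had 4 of 13 members higher and 5 lower. The inhibitor gene Cdkn1a was higher, at 35.6 against 4.98 CPM, and the cyclin gene Ccnd3 was lower (log2 ratio -1.10). Of the 30 NMDA cells in the microglia- or macrophage-like cluster no comparison was made, since the uninjured library held 2. The cluster was led by S100a9, Spp1 and S100a8, genes of myeloid cells, followed by complement C1q genes. Its top 10 genes held 6 microglia or macrophage markers and 3 monocyte or neutrophil markers, S100a9, S100a8 and Lyz2. The cluster may therefore hold more than 1 myeloid cell type.

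The higher ribosomal protein share in NMDA Müller glia-like cells was weighed against technical causes. A difference between the libraries that acted alike on all cells would give rod-like cells a like change, but the odds ratio of ribosomal UMIs was 2.29 in rod-like cells (2.25 to 2.33) and 4.23 in Müller glia-like cells (4.22 to 4.24), which argues against it as the whole cause. Depth or damage of the cells was tested in 117 NMDA and 933 uninjured cells between 5267 and 9706 UMIs and with at most 10% mitochondrial UMIs. The list median was still 1.67 there and 75 of 80 genes were at least 2-fold higher, which argues against UMIs per cell as the whole cause. Damage cannot be decided so, since those 117 of 3239 NMDA cells lay far below their median of 20607 UMIs. Low-UMI NMDA cells may differ in state: the unnamed ones, at a median of 5775.5 UMIs, held 29.9% ribosomal UMIs. A shared technical part of unknown size is left open, since 12% of UMIs were ribosomal in the 124 NMDA rod-like cells with little glial RNA, above the 8.10% of uninjured rod-like cells. Among classes with few cells, the share was 10.5% against 4.61% in cone-like and 15.4% against 6.17% in astrocyte-like cells. In bipolar-like cells it was 6.41% against 5.76%. The NMDA treatment and the preparation of the library go together in this design, so a response of the glia to injury may account for the rest only as a hypothesis.

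Glial transcripts in NMDA rod-like cells were unevenly spread. A set of 171 genes with at least 100 CPM in NMDA Müller glia-like cells and at least 20-fold lower in uninjured rod-like cells, ribosomal and mitochondrial genes left out, made up 1.96% of NMDA rod-like UMIs. Evenly spread free RNA would leave 0.00064% of cells below 0.25 of that share, but 43.0% of 172 cells (35.5 to 50.8%) lay there, which argues against free RNA as the whole cause. Droplets with a rod and a whole Müller glial cell would be deep, but the 48 cells above the pooled share had a median of 2599.5 UMIs. Müller glia-like cells had 20607, so most of these 48 cells held no glial cell of typical depth. This outcome was close to fixed, since droplets with mostly glial UMIs would probably not be named rod-like. It says nothing on such droplets in other classes. Those 48 cells had a lower median share of rod markers than the other 124, 3.29% against 9.64%. Fragments of glia on rods, or damaged glia with rod RNA, may explain them and were not tested beyond the value of 43.0%. The set of 171 genes was chosen by low levels in uninjured rod-like cells. It therefore cannot tell glial RNA from genes that were higher in the rods themselves.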
